A study of Mus musculus with 8 samples.

How the data were processed

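RNA was measured in 8 libraries of mouse CD8+ T cells recovered from B16-OVA tumors, a melanoma line that expresses chicken ovalbumin. Per the labels' protocols, T cells of OT-I mice, whose receptor recognises an ovalbumin peptide, and of P14 mice, whose receptor recognises a peptide of lymphocytic choriomeningitis virus, were activated in culture with antibodies to CD3 and CD28, grown in IL-2, mixed in equal numbers and injected into the same tumor-bearing animals. Tumors of several animals were pooled before CD8 enrichment, and live cells were sorted on CD8 with CD45.1 (OT-I) or with Thy1.1 (P14). Poly(A) RNA was amplified with a whole-transcriptome amplification kit. RNA had been extracted with either of 2 kits, and which library used which kit is not given in the sources used here. Groups were taken from the sample titles: 3 OT-I and 5 P14 libraries. The labels do not tie a library to particular animals or to a sorting day, so p-values measure the spread between these pooled samples.

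The deposited file held whole-number read counts per gene for each library, without normalization, and the length of each gene. Per the submitters' processing notes, STAR and featureCounts were used with the mouse build mm10. Their versions, the annotation release, strandedness, and the treatment of duplicates and of reads with several alignments are not given in the sources used here. The layout of the file is that of featureCounts, per the file headers. If strand was not used, reads from overlapping genes and antisense partners cannot be told apart, and amplification duplicates may be counted as separate reads. Coordinates are those in the deposited file. Gene symbols were attached by Ensembl identifier from GENCODE release M21, which held 98.8% of the 45706 identifiers (45143); 83.2% of those had the same start and end there. No count belonged to a row without a gene, and 25006 genes had no count in any library.

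Total counts were 8823794, 9575675 and 6240437 in OT-I libraries 1 to 3 and 8305681, 4947850, 10324286, 5549261 and 11978070 in P14 libraries 1 to 5. A single count was worth between 0.0835 CPM (P14 5) and 0.202 CPM (P14 2). Intervals and floors given for low counts are 95% Poisson intervals and 3 counts over a group, and they cover counting error only. No pair of libraries held identical values. The closest pair, P14 1 and P14 2, differed by a chi-square of 24.5 per gene over 11718 genes, more than counting noise gives, so no library repeats the counts of another. This does not exclude that some came from the same RNA, and all 8 were taken as replicates by their titles.

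The groups were compared with the edgeR 4.0.16 quasi-likelihood F test (robust) on the deposited counts in R 4.3.3, with TMM scaling, the filterByExpr filter by group and group as the only term. This left 11898 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called higher or lower in OT-I, and log2 fold changes are OT-I over P14 with their standard errors (SE). The SE were derived as the absolute log2 fold change divided by the square root of the F statistic, so they are approximate. CPM values are scaled by the TMM factors and given as mean ± SD over the libraries of a group. The 30 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 30 lists. For each list the number of called members is given over all tested genes and, where it differs, adjusted over the list alone.

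Genes named in the text were chosen by a rule also set before the data were examined. It took the 10 largest positive and 10 largest negative log2 fold changes among called genes whose groups did not overlap and whose mean was at least 5 CPM, leaving out predicted genes and receptor or immunoglobulin segments. It also took the 4 members of each list with the smallest p, the identity genes, and these genes set in advance: Pdcd1, Havcr2, Lag3, Ctla4, Tox, Nr4a1, Nr4a2, Nr4a3, Tcf7, Il7r, Gzmb, Prf1, Ifng, Tnf and Mki67. A few genes that the rule selects are not reported here.

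The tests were run on simulated counts, 3 libraries against 5, with 11398 genes tested. Counts came from a single draw that used the real means, the library sizes and the dispersions that edgeR had estimated. edgeR recovered 0% of genes changed 2-fold, 20.4% of those changed 4-fold, 50% at 8-fold and 70.8% at 16-fold, with 6.8% of its calls false. DESeq2 recovered 0%, 40.8%, 72.9% and 83.3% with 38.7% false, and limma voom 0%, 10.2%, 41.7% and 50% with 2% false. The simulation of camera called the shifted list (adjusted p = 6.64e-13) and 0 of the others. Simulated genes varied independently of each other, so it cannot show how often camera errs on lists whose members move together. The estimated correlation within the real lists reached 0.77 (mitochondrially encoded genes).

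Alternatives set in advance were size factors of DESeq2 (RLE) or upper quartile factors within edgeR, no low-count filter, a stricter filter (5 CPM in at least 3 libraries), DESeq2 1.42.0, limma voom with sample quality weights, a minimum fold of 1.5 (glmTreat), a replicate block, and each library left out in turn. Chosen after seeing the data were 5 more. The first had the Xist class as a covariate, because donor sex was not labelled: libraries OT-I 1, OT-I 3, P14 1, P14 2 and P14 3 held Xist at over 100 CPM (high Xist), and OT-I 2, P14 4 and P14 5 at 3.4 CPM or less (low Xist). Y-linked genes summed to 15.9 to 71.4 CPM in the low Xist class, and to 0 to 4.6 CPM in the other, with P14 1 at 4.6 and P14 3 at 2.8 CPM. The others were a surrogate variable from sva 3.50.0, leaving out both OT-I 2 and P14 4, and each class of libraries alone. The surrogate variable was not used for the list tests.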

Results

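Gene expression was measured by RNA sequencing in OT-I and P14 CD8+ T cells that had been transferred together into mice with B16-OVA melanomas and sorted from the tumors. OT-I cells carry a transgenic receptor for an ovalbumin peptide made by the tumor. P14 cells carry a receptor for a viral peptide that the tumor does not make, and so served as bystander cells of the same tumors. The title of the series names exhaustion, a state of reduced function that T cells enter under lasting antigen exposure, as its subject. The comparison asks which transcripts differ between tumor-infiltrating T cells that can and cannot recognise tumor antigen. The 3 OT-I libraries held 6240437 to 9575675 counts and the 5 P14 libraries 4947850 to 11978070. Between 11929 (P14 4) and 16490 (OT-I 1) genes had at least 1 count.

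The Vβ genes of the receptors separated the groups as labelled. Trbv12-1, which encodes the Vβ5 chain of the OT-I receptor (ENSMUSG00000095574.2, chromosome 6, 41113550 to 41114067, mm10), had 957, 856 and 45 counts in the OT-I libraries and 1, 0, 2, 0 and 0 counts in the P14 libraries. Trbv13-3, which encodes the Vβ8.1 chain of the P14 receptor (ENSMUSG00000076470.1, chromosome 6, 41130147 to 41130585), had 1, 0 and 0 counts in OT-I and 764, 748, 1534, 247 and 153 in P14. The Vα segment Trav14-1 (ENSMUSG00000076840.4, chromosome 14, 53554022 to 53554558) had 22, 14 and 7 counts in OT-I and 6675, 6324, 7677, 9260 and 5168 in P14. These 3 genes were called by edgeR (adjusted p = 0.00102, 0.00118 and 0.000257). Trbv12-2 had 750, 770, 1739, 262 and 189 counts in P14 and 1, 0 and 0 in OT-I, close to the counts of Trbv13-3 in each library; counts alone cannot show whether they come from transcripts of Trbv12-2. Within the Trav14, Trbv12 and Trbv13 families, 95.1% of the 50-base stretches of Trav14-1 were found in no other member, as were 98.8% of those of Trbv12-2 and 99.7% of those of Trbv13-3, while Trav14d-1 and Trav14n-1 had no such stretch. Trav14 values are therefore uncertain where counting could split or drop reads shared between copies. Both receptors use a Vα2 chain, from the Trav14 family, so Trav14-1 was not a check of the labels. Its low counts in OT-I do not show that OT-I cells lacked such a chain. Low counts were listed for Trbv13-2 (1, 1 and 1 in OT-I and 0, 8, 61, 13 and 4 in P14), Trbv13-1 (0, 1 and 0, and 2, 1, 15, 0 and 59), Trav14-2 (0, 25 and 6, and 0, 22, 64, 50 and 20) and Trav14-3 (4, 1 and 4, and 6, 1, 27, 2 and 40), and Trav14d-3-dv8 was listed at 0 in all 8 libraries. The genes of the sorted proteins did not pass the edgeR test: Ptprc (CD45) had a log2 fold change of -0.58 ± 0.61 (SE, adjusted p = 0.729), Thy1 -0.32 ± 0.56 (adjusted p = 0.855), Cd8a 0.43 ± 0.43 (adjusted p = 0.705) and Cd8b1 -0.65 ± 0.46 (adjusted p = 0.561). Cd3e, whose protein was not sorted on, did not pass either (-0.22 ± 0.38, edgeR adjusted p = 0.854).

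In OT-I cells from the tumor, 3 of 12 inhibitory receptors, 7 of 19 early genes induced through the T cell receptor, 19 of 51 genes of G2 and M phase and 17 of 44 genes of S phase were higher than in P14 cells from the tumor, and 13 of 28 type I interferon response genes were lower. Camera called each of these 5 lists; with an estimated correlation it called the cell division and interferon lists (adjusted p = 0.0321, 0.0292 and 0.0435) and not the first 2 (adjusted p = 0.0798 and 0.139). Pdcd1, which encodes the inhibitory receptor PD-1, stood at 237 ± 137 CPM in OT-I (SD, n = 3) and 15.3 ± 11.9 CPM in P14 (n = 5). Ube2c, which drives exit from mitosis, stood at 420 ± 124 CPM in OT-I and 45.4 ± 14.6 CPM in P14. Irf7, a master regulator of type I interferon responses, stood at 55.5 ± 3.75 CPM in OT-I and 762 ± 221 CPM in P14. Of 11898 genes tested, edgeR called 337 (2.83%), 187 higher and 150 lower in OT-I, and 1925 had an unadjusted p under 0.05. Every OT-I library lay beyond every P14 library for 332 of the 337, and for 13.6% of all tested genes, where chance gives 3.57%. The smallest absolute log2 fold change among the called genes was 1.61 and their median 3.14, against a biological coefficient of variation of 77.6%.

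The count of called genes depended on the libraries and the tool, while the direction of the 337 genes held in each setting that tested them. Called genes are picked for large differences, and 332 of these had groups without overlap, so a constant direction adds little support. The count was 142, 164 and 96 without OT-I 1, OT-I 2 or OT-I 3, and 216, 149 and 176 without P14 1, P14 2 or P14 3. DESeq2 called 1042 genes, 44.8% of them higher in OT-I where edgeR had 55.5%, and limma voom called 848. Within the libraries with Xist over 100 CPM (high Xist, 2 OT-I and 3 P14) edgeR called 705 genes, and within the others (low Xist, 1 OT-I and 2 P14) 106, where the lone OT-I library is assumed to vary like the P14 libraries.

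**Figure D1:**
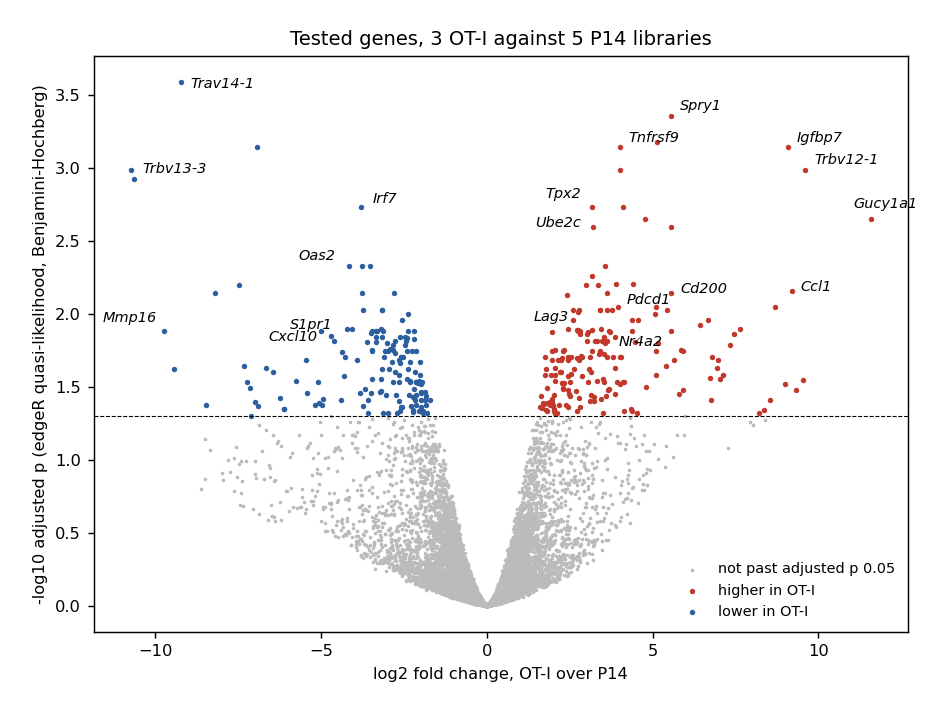
Log2 fold change of each tested gene (x axis, OT-I over P14) against -log10 of the edgeR adjusted p (y axis), with 187 genes higher in OT-I in red, 150 lower in blue and genes that did not pass in grey; the dashed line marks an adjusted p of 0.05. No called gene has an absolute log2 fold change below 1.61.

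The 10 genes with the largest increases in OT-I, by the rule for named genes, had means of 0.88 CPM or less in P14. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase (ENSMUSG00000033910.11, chromosome 3, 82092427 to 82145789), had 329, 207 and 515 counts in the OT-I libraries and 0 counts in all 5 P14 libraries, at least 584-fold higher against a floor of 3 counts over the group. Igfbp7, a secreted binding protein, had a ratio of 676 (95% counting interval 231 to 3280), Spin4 a ratio of 732 (131 to 29000), Syna, an envelope gene of retroviral origin, a ratio of 269 (74.0 to 2230), and Mlf1 a ratio of 192 (65.1 to 935). The chemokine Ccl1 had a log2 fold change of 9.19 ± 1.39 (SE), the serpin Serpinb9b 7.33 ± 1.39, Ccdc184 6.94 ± 1.44, the cytokine Csf2 (GM-CSF) 6.80 ± 1.36 and the IL-33 receptor Il1rl1 6.67 ± 1.13. Ccl1 (379 ± 620 CPM), Csf2 (101 ± 157 CPM) and Serpinb9b (55.5 ± 81.3 CPM) varied widely among the 3 OT-I libraries. Without OT-I 2, Ccl1 had a log2 fold change of 5.02 and was still called (edgeR adjusted p = 0.044). Csf2 then had 3.56 and Serpinb9b 4.72, and neither passed (adjusted p = 0.303 and 0.216); Csf2 was also lost without P14 2. Calls were lost for Spin4 without OT-I 1 (0.0837), for Il1rl1 and Syna without OT-I 3 (0.0788 and 0.0552), for Mlf1 without OT-I 1, OT-I 2, OT-I 3 or P14 2 (up to 0.0771) and for Ccdc184 without OT-I 2, OT-I 3, P14 2 or P14 3 (up to 0.159).

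Among the largest decreases, Mmp16, a membrane metalloproteinase, had 0 OT-I counts and was at least 115-fold lower. Cdh1, which encodes E-cadherin, fell from 41.5 ± 26.8 CPM in P14 to 0.25 ± 0.35 CPM in OT-I (log2 fold change -7.46, edgeR adjusted p = 0.00635). Lrrc75b was lower with a ratio of P14 to OT-I of 383 (68.5 to 15200) and Nhsl2 with a ratio of 109. Another 5 are known from myeloid cells. They were Slamf8 (0 OT-I counts, at least 77.3-fold lower) and the surface receptor genes Clec4e (ratio 191), Clec4a2 (ratio 126), Nfam1 (ratio 213) and Pilrb1 (ratio 109). Those 5 and Nhsl2 each lost the edgeR call when OT-I 1, OT-I 2 or OT-I 3 was left out. They did so also without P14 1 (Nfam1), P14 1 or P14 2 (Slamf8, Clec4e and Clec4a2), P14 2 or P14 3 (Pilrb1) and P14 1, P14 2, P14 3 or P14 4 (Nhsl2), with adjusted p up to 0.166. Mmp16, Lrrc75b and Cdh1 were called with each library left out in turn.

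Of 12 inhibitory receptors, 3 were higher in OT-I, none was lower and 9 did not pass; adjusted over the list alone, 6 were higher. Pdcd1 (ENSMUSG00000026285.7, chromosome 1, 94038305 to 94052553) had a log2 fold change of 3.96 ± 0.63 (SE, edgeR adjusted p = 0.009), Lag3 2.72 ± 0.47 (adjusted p = 0.0129) and Cd200 5.56 ± 0.86 (adjusted p = 0.00718). Lag3 stood at 241 ± 138 CPM in OT-I and 36.6 ± 14.5 CPM in P14, and Cd200 at 141 ± 45.3 and 2.90 ± 3.02 CPM. These 3 genes were called with each library left out in turn. Havcr2, which encodes TIM-3, had a log2 fold change of 2.33 ± 0.69 and did not pass (edgeR adjusted p = 0.0926), and Ctla4 was at 61.6 ± 9.06 CPM in OT-I and 63.3 ± 35.3 CPM in P14 (log2 fold change -0.04 ± 0.51). The list had a median log2 fold change of 1.45 and a camera adjusted p of 0.00157, which became an adjusted p = 0.0798 with an estimated correlation.

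Of 19 early genes induced through the T cell receptor, 7 were higher and 12 did not pass (8 higher, adjusted over the list alone). Spry1, a feedback inhibitor of receptor signalling (ENSMUSG00000037211.10, chromosome 3, 37639947 to 37644598), rose from 1.66 ± 0.60 CPM in P14 to 79.5 ± 12.4 CPM in OT-I (log2 fold change 5.54 ± 0.52, edgeR adjusted p = 0.000435). The costimulatory receptor genes Tnfrsf9 (4-1BB) and Tnfrsf4 (OX40) had log2 fold changes of 4.01 ± 0.42 and 4.76 ± 0.61, and the transcription factor Egr2 of 4.39 ± 0.74. The list's camera adjusted p was 7.11e-07, and its adjusted p = 0.139 with an estimated correlation. Tnfrsf9 and Tnfrsf4 were also the 2 higher members of 11 costimulatory receptors, of which 9 did not pass (list median 0.46, camera adjusted p = 0.189). Of 15 transcription factors associated with exhaustion, 6 of which are in another list, 5 were higher, 1 lower and 9 did not pass, with the same counts adjusted over the list alone. Nr4a2 stood at 496 ± 99.1 CPM in OT-I and 37.6 ± 34.9 CPM in P14 (log2 fold change 3.72 ± 0.67, edgeR adjusted p = 0.0132). Nr4a3 had a log2 fold change of 3.12 ± 0.62, Irf4 of 2.33 ± 0.45 and Tox, a chromatin factor needed for exhaustion, of 2.50 ± 0.57 (adjusted p = 0.0363). Nr4a2 was called with each library left out in turn. Calls were lost for Irf4 without OT-I 1 or P14 3 (edgeR adjusted p up to 0.0589), for Nr4a3 without OT-I 1, OT-I 2, P14 2 or P14 3 (up to 0.0625) and for Tox without OT-I 2, OT-I 3, P14 1, P14 2 or P14 3 (up to 0.157). The lower member was Id2 (log2 fold change -2.63), named after its values were seen, and Nr4a1 did not pass (1.21 ± 0.62, adjusted p = 0.366). The list had a camera adjusted p of 0.00087 and an adjusted p = 0.139 with an estimated correlation.

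**Figure D2:**
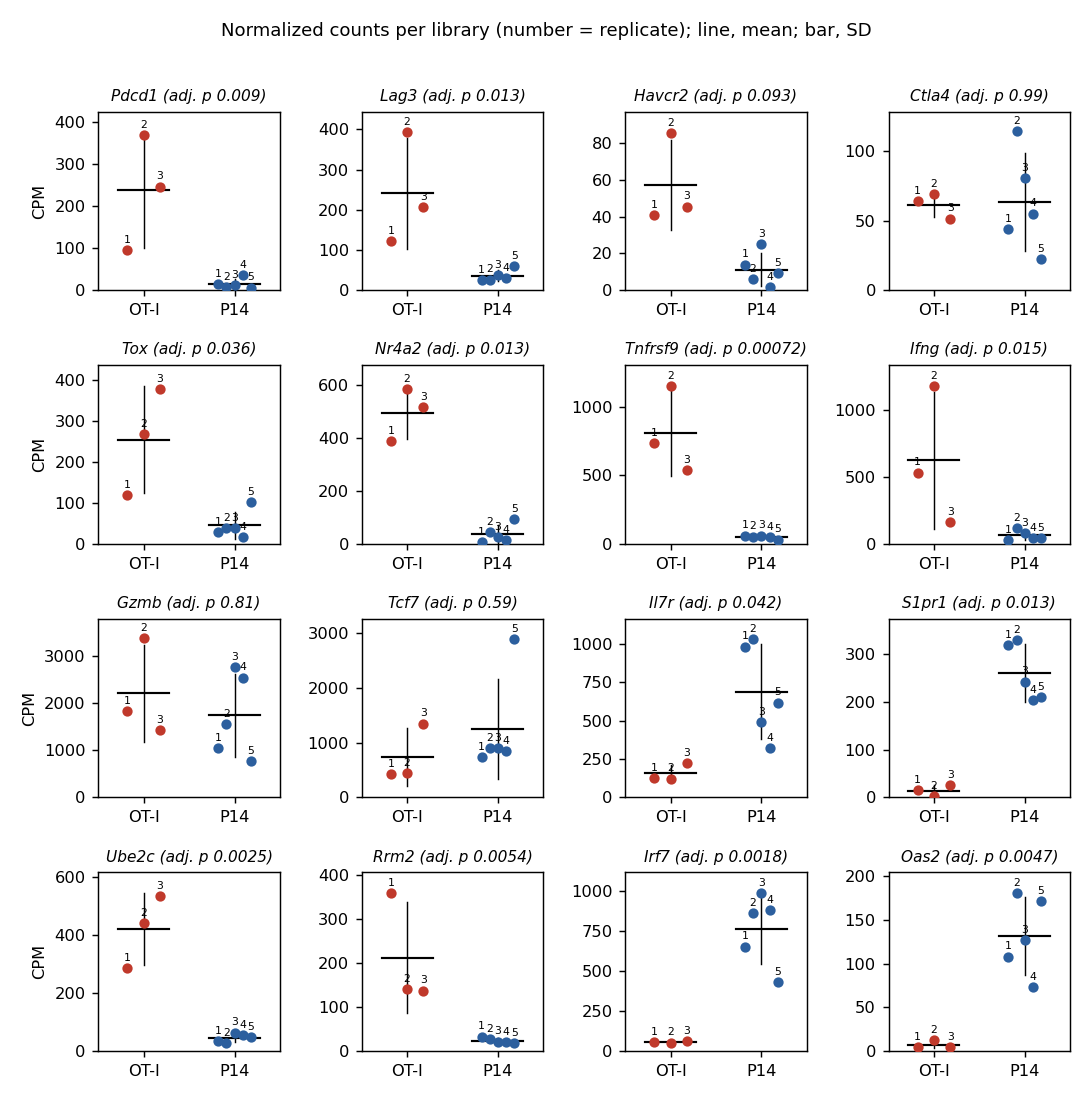
Normalized counts in CPM (y axis) of 16 genes in each library, with replicate numbers beside the points, a horizontal line at the group mean and a vertical bar of 1 SD on either side, for 3 OT-I (red) and 5 P14 (blue) libraries. Tnfrsf9, Ube2c and Irf7 separate all libraries of the groups, while Ctla4, Gzmb and Tcf7 overlap.

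Of 14 tested cytokine and chemokine genes of T cells, 6 were higher, 1 lower and 7 did not pass (8 higher and 1 lower, adjusted over the list alone). Xcl1 stood at 1058 ± 1041 CPM in OT-I and 31.2 ± 30.5 CPM in P14, Ccl3 at 807 ± 878 and 54.8 ± 34.4 CPM, and Ifng at 623 ± 512 and 62.8 ± 36.7 CPM. OT-I 2 carried much of this: without it Ifng had a log2 fold change of 2.47 in place of 3.31, and Ifng, Ccl3 and Xcl1 no longer passed the edgeR test (adjusted p up to 0.0615); Xcl1 was also lost without P14 2. Tnf did not pass (log2 fold change 0.85 ± 0.56), and the lower member, named after its values were seen, was Ccl5 (-3.20). The camera adjusted p was 0.000138, and the adjusted p = 0.291 with an estimated correlation. Of 17 cytotoxic effector genes, 2 were higher and 15 did not pass (3 higher and 1 lower, adjusted over the list alone). The 2 were Serpinb9 (log2 fold change 2.06 ± 0.40) and Serpinb6b (2.80 ± 0.57), serpins that inhibit granule proteases. Serpinb9 lost its edgeR call without OT-I 1, OT-I 2 or P14 2 (adjusted p up to 0.0629) and Serpinb6b without OT-I 2 or P14 2 (up to 0.0679). Gzmb, which encodes granzyme B, stood at 2205 ± 1027 CPM in OT-I and 1733 ± 885 CPM in P14 (log2 fold change 0.35 ± 0.49, edgeR adjusted p = 0.811), and Prf1, perforin, had 1.35 ± 0.61 (adjusted p = 0.297). This list's median was -0.18, its mean 0.24 and its camera direction upward (adjusted p = 0.58).

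Of 20 genes of naive and memory T cells, 5 were lower in OT-I and 15 did not pass (3 higher and 7 lower, adjusted over the list alone). S1pr1, the receptor that lets T cells leave tissue, fell from 261 ± 60.0 CPM in P14 to 14.2 ± 12.0 CPM in OT-I (log2 fold change -4.20 ± 0.73, edgeR adjusted p = 0.0126), and Klf2, a transcription factor that drives S1pr1, had -3.31 ± 0.59. The others were Ltb (-2.65 ± 0.58), Bcl2 (-1.96 ± 0.43) and Il7r, the IL-7 receptor (-2.14 ± 0.51, adjusted p = 0.042). Calls were lost for Klf2 without OT-I 3 (edgeR adjusted p = 0.0696), for Ltb without OT-I 1, OT-I 2, OT-I 3, P14 2 or P14 3 (up to 0.124), and for Bcl2 and Il7r without OT-I 1, OT-I 2, OT-I 3, P14 1, P14 2 or P14 3 (up to 0.165). Tcf7, which encodes TCF-1, did not pass (-0.76 ± 0.58, adjusted p = 0.594). The list's camera adjusted p was 0.0252, 0.126 without P14 5, 0.154 with the replicate block, 0.25 within the high Xist libraries, and the adjusted p = 0.57 with an estimated correlation. Of 16 homing and residency genes, 2 were higher, 3 lower and 11 did not pass (4 and 9, adjusted over the list alone). Rgs16, a regulator of chemokine receptor signalling, had a log2 fold change of 5.54 ± 0.72. Ccr8, named after its values were seen, had 5.92. The lower genes were Ly6c2 (-2.59 ± 0.52), Cxcr3 (-2.65 ± 0.54) and Zfp683, which encodes HOBIT (-3.90 ± 0.79). Calls were lost for Ly6c2 without OT-I 1, OT-I 2 or OT-I 3 (edgeR adjusted p up to 0.099), for Cxcr3 without OT-I 1, OT-I 3 or P14 3 (up to 0.105) and for Zfp683 without OT-I 1, OT-I 2, OT-I 3 or P14 3 (up to 0.0849). The camera adjusted p of 0.0397 was lost without OT-I 1 (0.0811), OT-I 3 (0.155), P14 2 (0.0596), P14 3 (0.0586) or P14 4 (0.1), and the adjusted p = 0.438 with an estimated correlation. None of 17 NF-kB pathway genes passed (list median -0.17, camera adjusted p = 0.652).

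Cell division genes were higher in OT-I. Of 51 genes of G2 and M phase, 50 had a positive log2 fold change, 19 were higher, none was lower and 32 did not pass (41 higher, adjusted over the list alone). Tpx2, a spindle factor, stood at 200 ± 6.65 CPM in OT-I and 21.9 ± 5.68 CPM in P14 (log2 fold change 3.19 ± 0.39, edgeR adjusted p = 0.00184). Ube2c (3.21 ± 0.42), Cdca8 (3.57 ± 0.50) and Ccnb2, a mitotic cyclin (3.37 ± 0.50), were close to it in size. Of 44 S phase genes all had a positive log2 fold change, 17 were higher and 27 did not pass (32 higher, adjusted over the list alone). E2f8 had a log2 fold change of 4.03 ± 0.46, Cdc45, a part of the replicative helicase, 3.91 ± 0.57, and Rrm2, which makes DNA precursors, 3.17 ± 0.46. The medians of the lists were 2.70 and 2.02, with camera adjusted p of 5.25e-24 and 7.98e-22, and the adjusted p = 0.0321 and 0.0292 with an estimated correlation. Within the high Xist libraries the camera adjusted p were 5.50e-23 and 6.74e-19. Mki67 did not pass (log2 fold change 3.18 ± 1.03, edgeR adjusted p = 0.127) and had -3.80 within the low Xist libraries. Melanoma cell markers, which dividing tumor cells would bring, summed to 344 ± 387 CPM in OT-I and 603 ± 865 CPM in P14. The higher P14 mean comes from P14 1 at 2136 CPM, as the other P14 libraries held 96.9 to 377 CPM.

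Genes of metabolism mostly did not pass. None of 18 glycolysis genes passed (list median 0.80, camera adjusted p = 0.00383, 0.0509 without OT-I 2, and adjusted p = 0.28 with an estimated correlation), and Ldha had 1.31 ± 0.41. None of 32 oxidative phosphorylation genes passed (median 0.55, camera adjusted p = 0.00667, 0.156 without OT-I 2, 0.165 without P14 5, 0.0521 with the replicate block, 0.293 within the high Xist libraries, and adjusted p = 0.64 with an estimated correlation). Of 20 cholesterol synthesis genes 1 was higher and 19 did not pass (2 higher, adjusted over the list alone; camera adjusted p = 0.00887, and adjusted p = 0.139 with an estimated correlation). None of 15 hypoxia genes (median 0.18, camera adjusted p = 0.352) or of 57 cytosolic ribosomal protein genes (median 0.01, camera adjusted p = 0.93) passed.

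Type I interferon response genes were lower in OT-I. All 28 had a negative log2 fold change, 13 were lower, none was higher and 15 did not pass (24 lower, adjusted over the list alone). Irf7 (ENSMUSG00000025498.12, chromosome 7, 141262706 to 141266481) had a log2 fold change of -3.78 ± 0.47 (edgeR adjusted p = 0.00184). Oas2, an antiviral RNA sensor, fell from 132 ± 44.7 CPM in P14 to 7.33 ± 4.34 CPM in OT-I (-4.16 ± 0.59, adjusted p = 0.00467), and Mx1 (-3.13 ± 0.56) and the ubiquitin-like modifier Isg15 (-3.14 ± 0.58) were also lower. Mx1 lost its edgeR call without OT-I 2 or OT-I 3 (adjusted p up to 0.0716) and Isg15 without OT-I 3 (0.0777). The list had a median of -2.24 and a camera adjusted p of 1.09e-18, and the adjusted p = 0.0435 with an estimated correlation, which only this list and both cell division lists kept among the 16 of 30 lists that camera called. The camera adjusted p was 5.64e-19 within the high Xist libraries.

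Few markers of myeloid cells passed, all of them lower in OT-I. All 20 macrophage and monocyte markers had a negative log2 fold change (median -2.46, camera adjusted p = 1.98e-09, and adjusted p = 0.208 with an estimated correlation), 2 were lower and 18 did not pass (8 lower, adjusted over the list alone). The markers summed to 417 ± 101 CPM in OT-I and 1395 ± 604 CPM in P14, where the interferon genes summed to 2484 ± 530 and 8851 ± 1254 CPM. The groups overlapped in the markers: P14 3, at 477 CPM, lay within the OT-I range of 307 to 507 CPM. Its interferon genes summed to 9469 CPM. Csf1r, the receptor for macrophage colony-stimulating factor, stood at 0.89 ± 0.81 CPM in OT-I and 33.8 ± 27.6 CPM in P14, and Lyz2, an abundant lysozyme of macrophages, was at 134 ± 94.7 CPM in P14 with a log2 fold change of -3.60 ± 1.01 that did not pass (edgeR adjusted p = 0.0807). Csf1r lost its edgeR call without OT-I 1, OT-I 2, OT-I 3, P14 1, P14 2 or P14 5 (adjusted p up to 0.111). Of 9 dendritic cell markers 1 was lower, Itgax (-3.02 ± 0.57), and 8 did not pass (5 lower, adjusted over the list alone; median -2.30, also with Cd209a at its bound; camera adjusted p = 0.000138, and adjusted p = 0.139 with an estimated correlation). Of 2 tested neutrophil markers Il1b was lower (-5.08 ± 1.12) and Csf3r did not pass (both lower, adjusted over the list alone; camera adjusted p = 0.00145, 0.0574 without OT-I 3, 0.0692 with no low count filter, and adjusted p = 0.139 with an estimated correlation). All 12 neutrophil markers summed to 18.7 ± 29.8 CPM in OT-I and 39.7 ± 30.1 CPM in P14, and OT-I 2, at 53.1 CPM, exceeded 4 of the 5 P14 libraries. Itgax lost its edgeR call without OT-I 2 or OT-I 3 (adjusted p up to 0.0777), and Il1b without OT-I 1, OT-I 2, OT-I 3, P14 1 or P14 2 (up to 0.0884).

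**Figure D3:**
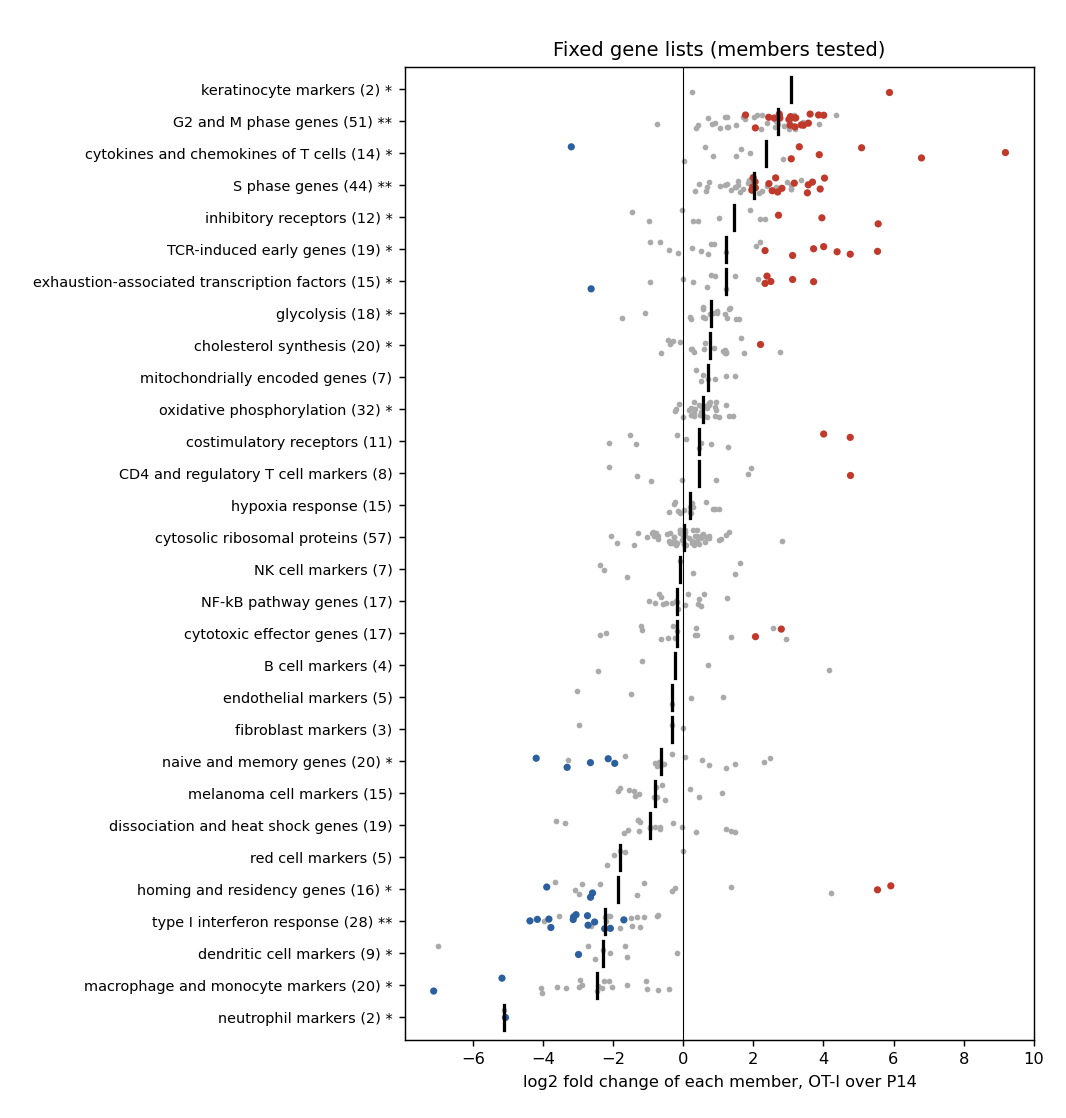
Log2 fold change (x axis, OT-I over P14) of each tested member of the 30 gene lists (y axis, number tested in brackets), with called members in red (higher) or blue (lower), others in grey and a black bar at the list median. An asterisk marks the 16 lists with a camera adjusted p under 0.05 and a double asterisk the 3 that also pass with an estimated correlation.

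Markers of most other cell types and measures of RNA quality did not pass in the main fit. None of 15 melanoma cell markers passed in edgeR (median -0.81, camera adjusted p = 0.352), though camera called the list lower without OT-I 1 (adjusted p = 0.0115) and with the replicate block (adjusted p = 0.0278). Within the low Xist libraries, which include a single OT-I library, camera called the melanoma and endothelial lists lower (adjusted p = 0.000405 and 0.0211). No member passed in edgeR among 4 B cell (1 higher, Ighd, adjusted over the list alone; camera adjusted p = 0.4), 7 NK cell (0.917), 3 fibroblast (0.443), 5 endothelial (0.517) and 5 red cell markers (0.517). These lists held 12, 12, 13, 12 and 10 markers, so the tests covered only part of each. The tested fibroblast markers included Thy1, the gene of a sorted protein. The tested NK cell markers included Gzma and Eomes, which are also in T cell lists above. The B cell list had a median of -0.24 with a mean of 0.31 and an upward camera direction. Of 8 markers of CD4 and regulatory T cells, Tnfrsf4, which activated CD8 cells also express, was higher and 7 did not pass (2 higher, adjusted over the list alone; camera adjusted p = 0.265). Of 2 keratinocyte markers Perp was higher (5.86 ± 1.13, lost without OT-I 2) and Krt10 did not pass (1 higher, adjusted over the list alone; camera adjusted p = 0.0238, 0.0509 without OT-I 2, 0.0538 without P14 1, and adjusted p = 0.201 with an estimated correlation). None of 19 dissociation and heat shock genes passed over all genes (median -0.95, camera adjusted p = 0.0957), and 1 was lower adjusted over the list alone. Camera called this list lower without OT-I 2, P14 1 or P14 5 (adjusted p = 0.0282, 0.0218 and 0.0352), with no low count filter (0.0218) and within the high Xist libraries (0.0436). None of 7 mitochondrially encoded genes passed (median 0.71, camera adjusted p = 0.183, higher at 0.0427 without OT-I 2), and their share of counts ran from 0.98% (P14 4) to 6.79% (OT-I 3).

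Within groups, the libraries also differed from each other. The first principal component of log2 CPM (31% of the variance) set OT-I 2 (139.9) and P14 4 (117.0) apart from the other 6 libraries (-76.2 to -11.4), and the next component (28.1%) separated OT-I (77.0 to 95.4) from P14 (-127.9 to -23.9). Without both of those libraries edgeR called 314 genes, 170 higher and 144 lower, of which 218 were among the 337.

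**Figure D4:**
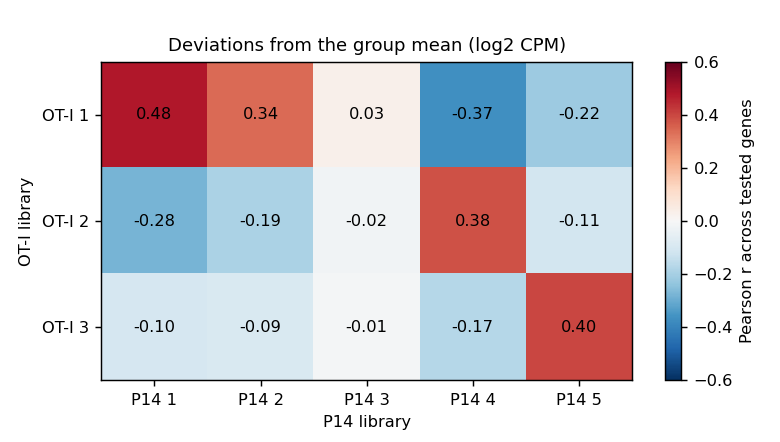
Pearson correlation across genes (color, with values in the cells) between the deviations of each OT-I library (rows) and each P14 library (columns) from the mean of its group. Genes are not independent replicates; the values run from -0.37 (OT-I 1 with P14 4) to 0.48 (OT-I 1 with P14 1), and OT-I 2 with P14 4 is at 0.38.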

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

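Among the tests of explanations here, both ratios of added CPM, the count of macrophage markers and the depth ranks were chosen only after the result was seen. Outliers were looked for among the 5 P14 libraries in 180 measures (named genes, list means and library measures), where chance marks about 1 in 20, and 17 measures had a library whose gap to the nearest other library exceeded 0.71 of the whole range on a log2 scale.

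P14 4 stood apart in 7 of them. Ptprc was at 416 CPM in P14 4 against 1940 to 2340 CPM in the others, Pdk1 at 28 against 82.2 to 118 CPM and mt-Nd1 at 1800 against 3450 to 4320 CPM. Higher values in P14 4 were those of Ldha (1400 CPM, others 508 to 654), Icam1 (296 CPM, others 88.8 to 110) and Cd79b (84.5 CPM, others 8.14 to 13.3). The geometric mean of the mitochondrially encoded genes was 1030 CPM in P14 4 against 2240 to 2830 CPM. P14 5 stood apart in Tcf7 (2890 CPM, others 740 to 902), Pecam1 (290 CPM, others 106 to 138), Rps21 (234 CPM, others 1650 to 2620), Gzma (4.02 CPM, others 158 to 504), Uqcrfs1 (13.1 CPM, others 102 to 152), Cdca8 (2.95 CPM, others 8.54 to 11.5) and the geometric mean of the oxidative phosphorylation genes (36.5 CPM, others 88.5 to 119). H2-Aa was at 34.8 CPM in P14 3 (others 164 to 296), Serpinb9b at 1.29 CPM in P14 3 (others 0 to 0.179) and Spin4 at 0.107 CPM in P14 1 (others 0). The Spin4 value is a single count, and any count against 0 in all other libraries meets this criterion.

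The 337 called genes were set against all splits of the 8 libraries into 3 and 5. Only the real split, 1 of 56, gave as many, and the highest of the others gave 1 gene. This argues against chance but cannot exclude it, since 1 of 56 is the smallest share that these splits can give. Each of the other splits mixes both groups, which adds the group difference to the spread within its parts and lowers its count. The splits also treat the libraries as independent, which the labels do not establish.

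P14 4 and OT-I 2 deviated from their groups together, with a correlation of 0.38 across genes. Gene length and GC content carried part of this and not the whole of it, since the correlation was 0.25 after both trends were removed. It was 0.37 without genes on X and Y, so those genes do not carry it. That value cannot speak to donor sex acting through other genes. OT-I 2 and P14 4 are both low Xist libraries, as is P14 5, which correlated at -0.11 with OT-I 2. Donor sex was not labelled and stays open. Low depth is argued against by OT-I 2, which has depth rank 3 in its group counted from the lowest. Both libraries had the fewest genes with a count in their groups (12631 in OT-I 2 and 11929 in P14 4), the lowest mitochondrial shares (1.64% and 0.98%) and the highest ribosomal protein shares (6.26% and 6.24%). Lower library complexity or RNA quality was not tested and stays open. A shared sorting day, extraction kit or pool of animals could also give such a pair and stays open, as the labels name none; a biological difference between tumors is likewise untested. Without both libraries 314 genes were called. Other pairs across the groups had correlations at least as high, OT-I 1 with P14 1 at 0.48 and OT-I 3 with P14 5 at 0.40. The latter was 0.37 after the length and GC trends were removed, and the causes of these pairs were not tested further.

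Lower type I interferon genes in OT-I came with negative log2 fold changes of macrophage and monocyte markers. RNA of macrophages or monocytes in the P14 sorts is a candidate source of the markers: 20 of 20 had a negative log2 fold change, although the sort took only cells positive for CD8 and Thy1.1, and the most abundant markers stayed low, with Lyz2 at 134 ± 94.7 CPM in P14. As the source of the interferon difference it is argued against by size, since the interferon genes added 6.51 times the CPM of the 20 markers (6367 against 977 CPM). With the marker level as a covariate the interferon list kept a camera adjusted p of 1.49e-15 and a median of -2.59, although that covariate is correlated with group (-0.79) and the fit with it called 5 genes. A lower exposure or response of OT-I cells to interferon may account for the interferon genes and was not tested further.

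The S, G2 and M phase genes were higher in OT-I, and dividing tumor cells in the OT-I sorts are an alternative source of that RNA, although the sort took only cells positive for CD8 and CD45.1. It is argued against by size: the genes added 10641 CPM in OT-I, 13.7 times the melanoma markers of the OT-I library with most of them (777 CPM). Those markers were not higher in OT-I on average (344 against 603 CPM in P14), but the higher P14 mean comes from P14 1 (2136 CPM). The other P14 libraries held 96.9 to 377 CPM of them, inside the OT-I range of 32 to 777 CPM. With the melanoma marker level as a covariate the larger camera adjusted p of both lists was 3.22e-20 and the smaller median 2.00. That fit decides nothing, since a covariate that is not higher in OT-I (correlation with group -0.22) could not remove a rise there. Division of OT-I cells in the tumor may be the reason, a hypothesis that was not itself tested.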

How the results depend on the processing

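All 79 called results (63 named genes and 16 lists) kept their direction in every alternative that gave them a value, and the 33 named genes and lists that turned direction somewhere were ones that had not passed. Results called for large differences seldom turn direction, so this adds little support. The 337 genes (187 higher, 150 lower) became 335 with RLE factors, 330 with upper quartile factors and 342 with the stricter filter. Larger moves were 641 (348 and 293) with no low count filter, 1042 (467 and 575) with DESeq2, 848 (523 and 325) with limma voom and quality weights, and 213 (124 and 89) with a minimum fold of 1.5. DESeq2 gave 87 genes no adjusted p, and in simulated data 38.7% of its calls were false. That simulation used dispersions estimated by edgeR, so it is not an even comparison of the tools. Leaving out each library in turn gave 96 to 388 genes, 70 to 226 higher and 26 to 162 lower; the count was lowest without OT-I 3 and highest without P14 4. Of the 63 called genes 29, and of the 16 called lists 10, passed in all 8 of those fits. Chosen after seeing the data, the Xist class as covariate gave 547 (302 and 245), 1 surrogate variable 759 (396 and 363), only the libraries with high Xist 705 (375 and 330), only those with low Xist 106 (39 and 67), and leaving out OT-I 2 and P14 4 gave 314. Fewer libraries entered the fits of subsets, yet the count rose to 705 within the high Xist libraries and to 388 without P14 4. The cause of the moves was not tested. With an estimated correlation 3 of the 16 lists passed. The estimates for these lists ran from -0.04 (inhibitory receptors) to 0.74 (neutrophil markers), against the preset 0.01. For inhibitory receptors the camera p rose from 0.000523 to 0.0106 although the estimate lay below the preset. A higher correlation among its members therefore does not account for that loss. The cause was not tested further.

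The deviations did not show a pairing by replicate number. Those of same-numbered libraries had correlations of 0.48, -0.19 and -0.01 for numbers 1, 2 and 3, and only number 1 correlated best with its own number. So few values cannot show whether the numbers mark shared pools of animals. The main fit took the libraries as unpaired, although cells of both groups were injected into the same animals. The fit with the replicate block called 577 genes (287 and 290), 295 of them among the 337. Numbers 4 and 5 occur only in P14, so the group difference in that fit rests on libraries 1 to 3 of each group. With the block, Cd3e (0.03), Igkc (3.97), Sparc (-0.76) and Thy1 (0.18) turned direction as log2 fold changes, as did the lists of NF-kB, NK cell, ribosomal protein and cytotoxic genes, at 0.827, 0.827, 0.826 and 0.968 for the p of camera in limma.

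Other values that turned direction are given here as log2 fold changes of genes and camera p of lists, and the cause was not tested. Sparc was -0.04 with upper quartile factors. With limma voom Igkc was 2.39, Pecam1 0.23 and Thy1 0.17. With no low count filter the NK cell list had 0.77, the ribosomal list 0.712 and the fibroblast list 0.543. With the Xist class Ctla4 was 0.03, Igkc was 0.76 and Sparc -0.63. Without OT-I 2 and P14 4 Krt10 was -0.38, and the ribosomal, endothelial and melanoma lists had 0.442, 0.649 and 0.689. In the high Xist libraries Gzmb was -0.09, Igkc 1.77, Krt10 -0.50, Pecam1 0.41, Sparc -0.06 and Tcf7 0.12, and the ribosomal, cytotoxic, endothelial and melanoma lists had 0.0386, 0.252, 0.727 and 0.876. In the low Xist libraries Ctla4 was 0.79, Egln3 -0.22, Ighm -0.12, Mki67 -3.80, Rps7 0.94, mt-Nd1 -0.15, mt-Nd2 -0.70 and mt-Nd6 -0.97, and the B cell, NF-kB, NK cell and mitochondrial lists had 0.39, 0.564, 0.554 and 0.606.

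With each library left out in turn the ranges that crossed 0 were Sparc -0.86 to 1.45, Thy1 -0.73 to 0.04, Gzmb -0.09 to 0.59, Ndrg1 -0.02 to 1.23, Krt10 -0.13 to 1.32, Ctla4 -0.25 to 0.27, Gpnmb -1.32 to 0.19, Mlana -2.84 to 0.21, Ptgds -4.12 to 0.48, Hba-a1 -8.13 to 0.34, Hbb-bs -11.71 to 1.95, Hbb-bt -9.57 to 0.97, Igkc -1.83 to 1.02 and Pecam1 -0.82 to 0.05. Lists that turned had camera p of 0.0816 to 0.883 (NF-kB), 0.143 to 0.722 (cytotoxic), 0.0363 to 0.861 (ribosomal), 0.00421 to 0.64 (melanoma), 0.0801 to 0.736 (endothelial), 0.0806 to 0.934 (red cell), 0.0199 to 0.844 (mitochondrial) and 0.195 to 0.999 (NK cell).

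Over all alternatives, 195 of 3015 gene values lost a call, 112 gained one, 47 turned and 2661 stayed as they were; of 539 list values 37 lost a call, 12 gained one, 31 turned and 459 stayed. Of the 37 list losses 13 were with the estimated correlation. Apart from the replicate block and the libraries left out in turn, the other losses had camera adjusted p of 0.0692 (neutrophil) and 0.0962 (keratinocyte) with no low count filter, 0.0528 (homing) with the Xist class, and 0.0838 (keratinocyte) without OT-I 2 and P14 4. They were 0.25 (naive and memory), 0.293 (oxidative phosphorylation) and 0.0757 (keratinocyte) in the high Xist libraries, and 0.787 (homing), 0.155 (neutrophil) and 0.0575 (keratinocyte) in the low Xist libraries. The 12 list gains were 5 of dissociation genes, 3 of melanoma markers and 1 of mitochondrial genes, and within the low Xist libraries, with a single OT-I library, endothelial markers (adjusted p = 0.0211), ribosomal genes (0.00643) and cytotoxic genes (0.0331). The stricter filter left 132 of the 145 tested named genes and 29 of 30 lists. Differences of 2-fold were not detectable at this number of libraries in the simulation, and genes with a few counts have folds bounded only by their counting intervals.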

Other observations

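Some interferon-inducible GTPases, which defend cells against vacuolar pathogens and lie outside the fixed lists, were lower in OT-I. All 17 tested members of the Gbp, Irgm, Igtp, Iigp and Tgtp genes had a negative log2 fold change (median -2.38), 5 were called by edgeR and 12 did not pass. Tgtp1 stood at 6.45 ± 4.12 CPM in OT-I and 59.1 ± 6.95 CPM in P14 (log2 fold change -3.19 ± 0.56), and Igtp at 123 ± 11.6 and 755 ± 342 CPM (-2.62 ± 0.48). Irgm1 (-2.40 ± 0.45), Irgm2 (-2.36 ± 0.42) and Tgtp2 (-2.01 ± 0.43) were the other called members. Igtp and Irgm2 overlap in the annotation, as do several Gbp genes, so their counts may not be separate. The receptor gene Ifngr1 was at 411 ± 87.3 CPM in OT-I and 1887 ± 203 CPM in P14 (-2.20 ± 0.39), the nucleotide hydrolase Samhd1 at 440 ± 100 and 1994 ± 341 CPM (-2.18 ± 0.41) and the chemokine Cxcl10 at 4.90 ± 4.90 and 121 ± 75.1 CPM (-4.62 ± 0.86), while Ifng itself was higher in OT-I (3.31 ± 0.62). These genes, and the 4 named in the next paragraph, were named after their values were seen. Camera gave the GTPases a p of 4.51e-10, and p = 0.0621 with an estimated correlation. The set was picked after called members had been seen and includes them, so this test does not decide whether the families differ as a whole.

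Some genes of amino acid metabolism were higher in OT-I. Psat1, of serine synthesis, stood at 269 ± 57.6 CPM in OT-I and 50.4 ± 9.17 CPM in P14 (log2 fold change 2.42 ± 0.38, edgeR adjusted p = 0.00743), and Bcat1, a branched-chain transaminase, at 55.4 ± 22.7 and 1.63 ± 1.59 CPM (5.06 ± 0.84). Among 15 other genes of serine, one-carbon and transaminase metabolism, 13 had a positive log2 fold change (median 1.42), and the mitochondrial folate enzyme Mthfd2 (2.27 ± 0.46) and Mthfd1 (2.04 ± 0.45) were called. The 15 were listed by pathway, because Psat1 and Bcat1 had been seen among the calls. Camera on those 15 gave an unadjusted p = 3.07e-06, and p = 0.014 with an estimated correlation.

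The tests of both gene families above were chosen after the result was seen, and the test below before. Both CD45.1 and Thy1.1 are alleles bred into the strain, so sequence variants carried along with Ptprc (chromosome 1) or Thy1 (chromosome 9) might give false calls near them. Within 20 Mb of either gene 8 of 346 tested genes were called (2.31%), against 2.85% elsewhere (odds ratio 0.81, p = 0.741, two-sided Fisher's exact test), which argues against a large contribution.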
